A study of Drosophila melanogaster with 9 samples.

How the data were processed

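Messenger RNA from whole adult Drosophila heads was sequenced in 9 libraries, 3 each from wild-type flies, from kdm5[A512P] flies and from kdm5[JmjC*] flies, all aged 3 to 5 days. Per the labels' protocols, stranded libraries were prepared from 500 ng of total RNA with 8 PCR cycles and read in pairs of 50 bases on an Illumina sequencer. Groups were taken from the library titles. The labels do not say whether the 3 libraries of a group came from separate collections of flies. The p-values of single genes therefore measure only the spread between these libraries, which may be technical. The p-values of gene lists, overlaps, chromosome arms and permutations take genes as the units. Genes are not independent replicates, so those p-values do not measure the spread between flies or libraries. The sex of the flies is not given in the sources used here.

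The analysis started from 2 tables of the authors' own comparisons, A512P against wild type and JmjC* against wild type, each with 17478 genes. STAR and DESeq2 are named in the submitters' processing notes, with no version or setting; the genome build, the annotation and the use of strand in counting are not given in the sources used here. The deposited signal of each gene is, per the file headers, a mean normalized count (DESeq2's baseMean), and it was identical in both tables for all 17478 genes, so both tables share 1 normalization. Per the file headers, the authors gave each gene a log2 fold change and its standard error (SE); the direction, mutant over wild type, is taken from the names of the comparisons. The deposited score is the Wald statistic, which equalled the log2 fold change divided by its SE to within 1.21e-13. The deposited p-value equalled the two-sided normal p of that score, and the authors' adjusted p-value was given for 11608 genes in the A512P table and 11898 in the JmjC* table. Genes with an adjusted p are called tested; the lowest mean normalized count among them was 3.75 for A512P and 2.90 for JmjC*. Another 82 genes had a score but no p-value in each table. The SE never exceeded 0.231, and among genes with a mean normalized count under 10 its median was 0.0911, below the 0.124 of all tested genes in the A512P table, so the fold changes are shrunken towards 0 and understate the change of weakly expressed genes.

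Values per library were not used here. The depth of each library is therefore unknown in this account; the mean normalized counts summed to 35167778 over all genes, and the gene with the highest count took 3.66% of that sum. Precision per gene is carried by the authors' SE, whose median over tested genes was 0.124 for A512P and 0.126 for JmjC*. Of 17478 gene identifiers, 17209 matched the Ensembl release 115 annotation of BDGP6.54; all of them lay on the same chromosome there and 98.2% had an identical exon length. Gene positions are those of BDGP6.54, and gene symbols are those of the authors' tables, several of which are older than the current ones.

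The test for each comparison was chosen before the data were examined, with a branch for each unit the tables could hold; with result tables in hand, the authors' log2 fold change, SE and adjusted p were read as they stood, and a gene with an adjusted p under 0.05 was called. No count model was refitted. Both mutants were compared directly through the difference of the 2 log2 fold changes over an SE of the square root of the summed squared SEs, as a two-sided normal test with Benjamini-Hochberg adjustment over the 11608 genes tested in both tables. That SE is an upper bound, because both comparisons use the same wild-type libraries. Overlap of calls was tested with one-sided Fisher exact tests per direction, beside the overlap of independent lists and 100 simulations of unchanged groups against shared controls, in which the scores of both comparisons correlate at 0.5. Chromosome arms were compared with two-sided Fisher exact tests, adjusted over 18 tests.

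In all, 37 gene lists were fixed before the data were examined: KDM5 with its interaction partners, other demethylases, synaptic genes, ion channels, learning and memory genes, neuropeptides, phototransduction, glia, circadian clock, antimicrobial peptides, immune signalling, heat shock proteins, antioxidant enzymes, glutathione S-transferases, cytochrome P450 genes, UDP-glycosyltransferases, cytosolic ribosomal proteins, mitochondrial ribosomal proteins, ribosome biogenesis, translation factors, oxidative phosphorylation, proteasome, glycolysis and citric acid cycle, storage and lipid metabolism, fat body, sex-biased head genes, muscle, midgut digestive enzymes, reproductive tissue, blood cells, cuticle, odorant-binding proteins, chemoreceptors, histones, cell cycle, juvenile hormone and ecdysone, and piRNA and heterochromatin. Each list was tested against all other genes with cameraPR of limma on the authors' score, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over 74 tests (37 lists in 2 comparisons). Members were counted by the authors' adjusted p and again adjusted over the list alone, and each median was ranked among 10000 random lists matched on mean normalized count. The difference between the mutants was tested over the same lists, with adjustment over 37 tests. An inter-gene correlation cannot be estimated from result tables, so camera with an estimated correlation and fry were not run; a preset correlation of 0.05 stands in.

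The genes named below follow a rule fixed in advance: per mutant the 8 largest rises and falls among called genes with a mean normalized count of at least 50, up to 4 called members per list with the smallest adjusted p, and kdm5; for the overlap the 8 genes with the largest shared change and up to 6 with opposite calls; for the direct comparison the 5 largest differences each way among called genes with a mean normalized count of at least 50. The weighing of explanations also names genes outside the rule; elsewhere they are said to be so. Alternatives were other thresholds (adjusted p under 0.01 and under 0.1), a mean normalized count of at least 10 or 50 with p re-adjusted, adjustment over all genes with a p-value, a fold change of at least 1.5, median-centred fold changes, a smaller SE for the direct test, and for the lists ranks, a correlation of 0.05 and a higher count minimum.

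The calling and direct tests were tested on simulated data over 11608 genes with 100 genes changed by each of 2 sizes. For A512P against wild type, 62% of genes changed by 0.5 on the log2 scale and 98% of those changed by 1.0 were recovered, with 12 false calls. For the direct comparison the SE bound recovered 28% and 92%, with 0 false calls. Normal noise was drawn with the authors' SEs, which the tests then used, so these figures do not check the SEs themselves. Simulated calls against wild type used a plain Benjamini-Hochberg adjustment in place of the authors' adjusted p. The list test found the 1 shifted list among 30, with 0 unshifted lists called. Genes were simulated as independent, so this does not show how the list test behaves where genes of a list are correlated. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 were used.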

Results

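KDM5 is a chromatin protein that removes methyl groups from histone tails through its Jumonji C (JmjC) domain. Heads of adult flies were profiled in 3 groups of 3 libraries each: wild type, kdm5[A512P], in which an alanine of KDM5 is replaced by proline, modelled on a missense allele of human KDM5C found in intellectual disability, and kdm5[JmjC*], whose protein lacks demethylase activity. The comparisons ask which transcripts change with each allele, and whether the disease-type allele and the enzyme-dead allele alter the same genes. All gene values below come from the authors' deposited tables, with their SE; the depth of single libraries was not used here.

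The kdm5 gene, named lid in the tables (FBgn0031759; BDGP6.54, chromosome 2L, 5989400 to 5999501, protein coding, minus strand), had a mean normalized count of 15978. Its log2 fold change in the authors' deposited table was -0.08 ± 0.095 (SE, adjusted p = 0.61) in A512P and -0.11 ± 0.095 (adjusted p = 0.431) in JmjC*, neither past the threshold. Both alleles change the protein, so the amount of mRNA does not check the labels.

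In heads of A512P flies, synaptic, ion channel, phototransduction, neuropeptide, ribosomal and glycolysis lists fell, while blood cell, cuticle and cell cycle lists rose. The authors' deposited table called 2436 of 11608 tested genes, 1183 higher and 1253 lower than wild type. Most changes were small: the called genes had a median fold change of 1.37 by the authors' deposited table, 846 changed at least 1.5-fold (613 up, 233 down) and 244 at least 2-fold (187 up, 57 down). The gene with the largest rise was St2, a sulfotransferase gene, 21.9-fold higher, and the gene with the largest fall was Cyp4s3, a cytochrome P450, 7.35-fold lower.

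St2 (FBgn0037665; chromosome 3R, 9251843 to 9253514) rose by 4.45 ± 0.21 on the log2 scale in the authors' deposited table (adjusted p = 2.92e-96). The next largest rise was that of roX1, a non-coding RNA of the X-chromosome dosage compensation complex (FBgn0019661; X, 3857230 to 3862697), which was 13.6-fold higher at a mean normalized count of 6184 (log2 3.77 ± 0.11, adjusted p = 3.89e-241, the authors' deposited table). CycB, the mitotic cyclin B (FBgn0000405; 2R, 22803521 to 22806948), was 7.74-fold higher, and Klp61F, a mitotic kinesin, 5.54-fold higher in the authors' deposited table. CG13646, CG6985, CG16734 and CG13720 completed the 8 largest rises, at log2 3.21, 2.97, 2.66 and 2.43 in the authors' deposited table. CG16734 (9255052 to 9256731) starts less than 2 kb from the end of St2 on the same strand, with the pseudogene CR16735 between them, so reads running on from one gene could be counted for the next. Cyp4s3 (FBgn0030615; X, 15113302 to 15116542) fell by 2.88 ± 0.21 on the log2 scale in the authors' deposited table (adjusted p = 4.40e-41). GILT3, of a lysosomal thiol reductase family, was 5.36-fold lower, and Sdr, a secreted decoy of the insulin receptor, 3.39-fold lower (log2 -1.76 ± 0.092, adjusted p = 3.79e-78, the authors' deposited table). The other large falls at a mean normalized count of at least 50 in the authors' deposited table were CG9589 (log2 -2.62), CG13704 (-1.80), Osi2 (-1.64), a5, an antennal protein (-1.57), and CG7879 (-1.52).

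Of 35 tested synaptic vesicle and active zone genes, 17 fell and 1 rose by the authors' deposited table (20 and 1 adjusted over the list alone), with a median log2 fold change of -0.21 (cameraPR adjusted p = 1.27e-05). Vmat, the vesicular monoamine transporter (log2 -0.37), VGlut, the vesicular glutamate transporter (-0.46), the vesicle GTPase Rab3 (-0.36) and the adhesion protein Nlg3 (-0.43) fell in the authors' deposited table, each with an SE of at most 0.11. Ion channel genes gave 13 falls and 0 rises among 38 (17 and 0 adjusted over the list alone; median -0.20, adjusted p = 1.47e-05). They included nAChRalpha2, a nicotinic acetylcholine receptor subunit (log2 -0.53), and Ca-alpha1D, a calcium channel subunit (-0.51), in the authors' deposited table. Phototransduction genes fell at 19 of 38 members and rose at 1 (21 and 1 adjusted over the list alone; median -0.23, adjusted p = 1.41e-06). The retinal genes laza (log2 -0.53), rtp (-0.37), ninaB (-0.45) and prom (-0.37) had the smallest adjusted p of this list in the authors' deposited table. Among 36 neuropeptide precursors, 13 fell and 4 rose (15 and 4 adjusted over the list alone; median -0.20, adjusted p = 7.29e-04). Tk (log2 -0.98 ± 0.13), AstA (-0.69), AstC (-0.66) and sNPF (-0.65) fell in the authors' deposited table. Learning and memory genes, which include fly orthologues of intellectual disability genes, gave 6 falls and 2 rises among 38 (8 and 2 adjusted over the list alone; median -0.16, adjusted p = 0.00338). That call ended with a preset correlation of 0.05 (adjusted p = 0.0619), as did the call of the 17 circadian clock genes, of which 4 fell and 0 rose, the same adjusted over the list alone (median -0.18, adjusted p = 0.0289, and 0.112 with the correlation of 0.05). The clock gene per was at log2 -0.79 ± 0.23 in the authors' deposited table (adjusted p = 0.00402), and Pdfr, the receptor of the clock peptide PDF, at -0.36.

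Among other head tissues, glial markers gave 3 falls and 1 rise among 18 (4 and 1 adjusted over the list alone; median -0.094, adjusted p = 0.315), and the glutamate transporter Eaat1 fell by 0.30 on the log2 scale in the authors' deposited table. Muscle genes fell at 7 and rose at 3 of 27 (9 and 3 adjusted over the list alone; median -0.098, adjusted p = 0.0629, and 0.0375 with ranks, downward). The actin gene Act79B was at log2 -0.87 and paramyosin, Prm, at 0.53 in the authors' deposited table. Of 21 fat body markers, 3 rose and 0 fell, the same adjusted over the list alone (median 0.19, adjusted p = 0.24). The pan-neuronal gene elav, named outside the rule as a tissue check, stood at log2 0.030 ± 0.12 in the authors' deposited table. The synaptic genes nSyb, Syt1 and brp, also named outside the rule, had negative values there, at log2 -0.27, -0.16 and -0.14.

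The clearest fall by list was that of the protein synthesis machinery. Of 86 cytosolic ribosomal proteins, 62 fell and 1 rose by the authors' deposited table (74 and 1 adjusted over the list alone), with a median log2 fold change of -0.35 (adjusted p = 2.55e-17). RpL3 (log2 -0.48 ± 0.081), sta (-0.56), RpL7 (-0.47) and RpS6 (-0.46) had the smallest adjusted p in the authors' deposited table. Ribosome biogenesis factors followed, with 22 of 34 lower and 1 higher (27 and 1 adjusted over the list alone; median -0.38, adjusted p = 1.84e-08). The nucleolar proteins Fib (log2 -0.80) and nop5 (-0.77) were among them in the authors' deposited table. Translation factors fell at 13 of 53 members and rose at 1 (14 and 2 adjusted over the list alone; median -0.11, adjusted p = 0.00112, and 0.0568 with a correlation of 0.05). The abundant elongation factor gene Ef1alpha48D was at log2 -0.51 in the authors' deposited table. Mitochondrial ribosomal proteins did not pass, with 4 lower and 0 higher of 72 (0 either way adjusted over the list alone; median -0.058, adjusted p = 0.153), although with ranks the list passed downward (adjusted p = 0.0353).

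Glycolysis and citric acid cycle enzymes fell at 8 of 28 members with 0 rises (9 lower and 1 higher adjusted over the list alone; median -0.16, adjusted p = 7.29e-04). Gpo-1, the mitochondrial glycerol phosphate oxidase (log2 -0.63), and the phosphofructokinase gene Pfk (-0.32) fell in the authors' deposited table. Oxidative phosphorylation subunits gave 9 falls and 0 rises among 100 (6 and 0 adjusted over the list alone; median -0.12, adjusted p = 0.00442, and 0.13 with a correlation of 0.05). Proteasome subunits gave 2 rises and 0 falls among 35 (0 either way adjusted over the list alone; median 0.093, adjusted p = 0.0983, and 0.00454 with ranks, upward).

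Of 16 blood cell markers, 8 rose and 0 fell, the same adjusted over the list alone (median 0.26, adjusted p = 0.00236). The receptor NimC2 (log2 0.93 ± 0.12), He (1.04) and the prophenoloxidase PPO3 (1.05) rose in the authors' deposited table. NimC1 and Pxn, abundant markers of the same cells named outside the rule, stood at log2 -0.034 and -0.059 in the authors' deposited table and did not pass. Immune signalling genes rose at 11 and fell at 1 of 44 (12 and 2 adjusted over the list alone; median 0.18, adjusted p = 0.00283, and 0.0619 with a correlation of 0.05). The complement-like genes Tep1 (log2 1.73 ± 0.20) and Tep2 (0.85) and the peptidoglycan receptor PGRP-SA (0.81) rose in the authors' deposited table. Antimicrobial peptides did not pass as a list, with 2 rises, Listericin (log2 0.97) and CG16836 (0.65), and 0 falls among 34 in the authors' deposited table (2 and 0 adjusted over the list alone; median 0.099, adjusted p = 0.104, and 0.0221 with ranks, upward).

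Cuticle and cell cycle lists also rose. Cuticle proteins gave 13 rises and 3 falls among 54 tested (14 and 4 adjusted over the list alone; median 0.13, adjusted p = 7.29e-04). Cpr76Bd was at log2 2.26 ± 0.13 and Cpr65Au at 2.25 ± 0.18 in the authors' deposited table. Cell cycle genes rose at 9 of 28 with 0 falls, the same adjusted over the list alone (median 0.15, adjusted p = 2.79e-04). Besides CycB, these included the mitotic regulators fzy (log2 1.71 ± 0.22) and Cdk1 (1.21) and the ribonucleotide reductase gene RnrS (1.02) in the authors' deposited table. In the piRNA and heterochromatin list 6 of 14 rose and 1 fell (7 and 1 adjusted over the list alone; median 0.26, adjusted p = 0.0353, and 0.112 with a correlation of 0.05). AGO3, an Argonaute of the piRNA pathway (log2 1.26 ± 0.20), and the helicase gene armi (0.59) rose, and del fell (-0.80), in the authors' deposited table. The list also holds the RNA interference genes AGO2, Dcr-2 and r2d2, and Dcr-2 was among the called rises (log2 0.42). The reproductive tissue list gave 6 rises and 2 falls among 28 (8 and 2 adjusted over the list alone; median 0.27, adjusted p = 0.0359, and 0.162 with a correlation of 0.05). Its name pattern also took Cp1, Cp190, Cp110, Acp1 and Acp65Aa, which are a protease, chromatin, centriole and cuticle genes, and without these 5 the list did not pass (adjusted p = 0.255).

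The sex-biased head list passed in A512P (4 rises and 1 fall among 14, the same adjusted over the list alone; adjusted p = 9.80e-05) through roX1, since its median was -0.0034 and its ranks gave an adjusted p of 0.348. The other RNA of the dosage compensation complex, roX2, named outside the rule, had a mean normalized count of 5.48 and stood at log2 -0.17 ± 0.19 in the authors' deposited table. The yolk protein genes Yp1, Yp2 and Yp3, transcribed mainly in females and also named outside the rule, held 5.44% of the summed mean normalized counts and stood at log2 -0.064, 0.25 and -0.074 in the authors' deposited table, none past the threshold. The KDM5 partner list did not pass (1 fall, foxo at log2 -0.35, and 0 rises among 16 in the authors' deposited table, the same adjusted over the list alone; median -0.021, adjusted p = 0.735). Other demethylases gave 4 rises and 0 falls among 13, the same adjusted over the list alone (median -0.033, adjusted p = 0.447), with CG43320 at log2 0.85 and PSR at 0.42 in the authors' deposited table. At an adjusted p under 0.01 the A512P calls numbered 1609.

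In heads of JmjC* flies, neuropeptide, synaptic, ribosomal and energy metabolism lists fell, while blood cell, immune signalling and cell cycle lists rose. The authors' deposited table called 3428 of 11898 tested genes (28.8%), 1692 higher and 1736 lower than wild type. The called genes had a median fold change of 1.38 by the authors' deposited table, 1138 changed at least 1.5-fold (738 up, 400 down) and 350 at least 2-fold (259 up, 91 down). The largest rise was that of mthl8, a receptor gene of the methuselah family, at 37.7-fold, and the largest fall again that of Cyp4s3, at 6.50-fold.

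The gene mthl8 (FBgn0052475; chromosome 3L, 22428 to 26308) rose by 5.24 ± 0.21 on the log2 scale in the authors' deposited table (adjusted p = 3.91e-130). In the same authors' deposited table roX1 was 18.4-fold higher (log2 4.20 ± 0.11, adjusted p = 1.51e-300) and CycB 10.2-fold higher (log2 3.35 ± 0.16, adjusted p = 4.23e-89). Spz4, a Spätzle family ligand (FBgn0032362; 2L, 11501715 to 11508649), was 6.87-fold higher, and the cuticle gene Cpr76Bd 6.70-fold higher, by the authors' deposited table. CG13646 (log2 3.02), CG14760 (2.62) and CG13720 (2.60) completed the 8 largest rises in the authors' deposited table. After Cyp4s3 (log2 -2.70 ± 0.21), the largest falls at a mean normalized count of at least 50 in the authors' deposited table were CG7906 (-2.36), Osi2 (-2.28), CG40298 (-2.24), the antisense RNA CR44030 (-2.03), a5 (-1.94), CG10357 (-1.93) and the olfactory receptor gene Ir75a (-1.84). CR44030 lies opposite another transcript and the use of strand in counting is not stated, so its value is uncertain.

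Neuropeptide precursors had the smallest adjusted p of all lists in JmjC*. Of 36 tested, 22 fell and 0 rose (24 and 0 adjusted over the list alone), with a median log2 fold change of -0.55 (adjusted p = 3.55e-18). By adjusted p its first member was AstC, the allatostatin C precursor, which fell by 1.41 ± 0.074 on the log2 scale in the authors' deposited table (adjusted p = 3.55e-77), followed by Proc (-0.90), Ms (-0.996) and Dh44 (-0.82). Tk, outside the rule for JmjC*, fell by 1.11 in the authors' deposited table. Synaptic genes fell at 23 of 35 with 0 rises (24 and 0 adjusted over the list alone; median -0.25, adjusted p = 4.32e-08). Snap25, a vesicle fusion protein, was at log2 -0.67, VGlut at -0.65 and Vmat at -0.54 in the authors' deposited table. Ion channels fell at 21 of 38 with 0 rises, the same adjusted over the list alone (median -0.27, adjusted p = 6.12e-06). Ca-alpha1D (log2 -0.58) and the glutamate receptor subunit GluRIA (-0.55) fell in the authors' deposited table. Phototransduction genes gave 15 falls and 3 rises among 38 (18 and 3 adjusted over the list alone; median -0.18, adjusted p = 0.00338, and 0.0619 with a correlation of 0.05). Its median ranked only at percentile 14.6 among random lists matched on mean normalized count. Within the phototransduction list retinin (log2 -0.73 ± 0.084) and the channel gene trp (-0.37) fell while its relative trpl rose (0.41 ± 0.088) in the authors' deposited table. Learning and memory genes fell at 11 and rose at 2 of 38 (12 and 2 adjusted over the list alone; median -0.17, adjusted p = 0.0029, and 0.0598 with a correlation of 0.05), among them klg (log2 -0.57) and Tequila (-0.54) in the authors' deposited table. Clock genes fell at 5 of 17 with 0 rises (7 and 0 adjusted over the list alone; median -0.19, adjusted p = 0.0154, and 0.0775 with a correlation of 0.05), and the clock neuropeptide gene Pdf was at log2 -0.85 ± 0.14 in the authors' deposited table.

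Tissue markers beside these lists were as follows. Muscle genes fell at 12 and rose at 2 of 27 (15 and 2 adjusted over the list alone; median -0.23, adjusted p = 8.30e-04). Act79B was at log2 -1.20 and TpnC41C at -1.04 in the authors' deposited table. Glial markers gave 8 falls and 3 rises among 18, the same adjusted over the list alone (median -0.18, adjusted p = 0.0932): the GABA transporter Gat was at log2 -0.66 and the blood-brain barrier gene moody at 0.42 in the authors' deposited table. Fat body markers gave 2 rises and 1 fall among 22, the same adjusted over the list alone (median -0.025, adjusted p = 0.987). The pan-neuronal gene elav stood at log2 -0.033 ± 0.12 in the authors' deposited table, and nSyb, Syt1 and brp at -0.24, -0.205 and -0.23.

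Ribosomal and metabolic lists fell in JmjC* too. Of 87 cytosolic ribosomal proteins, 76 fell and 1 rose (81 and 1 adjusted over the list alone; median -0.40, adjusted p = 5.34e-18). RpS6 was at log2 -0.55 and RpL3 at -0.50 in the authors' deposited table. Ribosome biogenesis factors fell at 20 of 34 with 0 rises (23 and 0 adjusted over the list alone; median -0.35, adjusted p = 8.34e-09). They included nop5 (log2 -1.02) and the pseudouridine synthase gene Nop60B (-0.93) in the authors' deposited table. Translation factors fell at 20 and rose at 3 of 53 (24 and 3 adjusted over the list alone; median -0.18, adjusted p = 1.36e-05). Mitochondrial ribosomal proteins gave 6 falls and 0 rises among 72 (3 and 0 adjusted over the list alone; median -0.11, adjusted p = 0.103, and 0.0177 with ranks, downward). Oxidative phosphorylation subunits fell at 35 of 100 and rose at 1 (37 and 1 adjusted over the list alone; median -0.27, adjusted p = 1.05e-06). The ATP synthase subunit gene ATPsynbeta was at log2 -0.50 ± 0.075 in the authors' deposited table. Glycolysis and citric acid cycle enzymes fell at 16 of 28 with 0 rises (18 and 0 adjusted over the list alone; median -0.27, adjusted p = 3.99e-06). The citrate synthase gene kdn was at log2 -0.50 in the authors' deposited table. Proteasome subunits rose as a list with 3 called members and 0 falls among 35 (2 and 0 adjusted over the list alone; median 0.14, adjusted p = 0.0156, and 0.123 with a correlation of 0.05).

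Among the lists that rose in JmjC*, blood cell markers gave 12 rises and 0 falls of 16, the same adjusted over the list alone (median 0.34, adjusted p = 7.92e-05). NimC2 was at log2 1.42 ± 0.12 and the clotting factor gene Hml at 0.63 ± 0.12 in the authors' deposited table. NimC1 and Pxn stood at log2 0.10 and -0.084 in the authors' deposited table and did not pass. Immune signalling genes rose at 18 and fell at 1 of 44 (19 and 1 adjusted over the list alone; median 0.21, adjusted p = 1.43e-04). Tep1 (log2 1.45), PGRP-SA (1.15) and GNBP2 (0.82) rose in the authors' deposited table. Antimicrobial peptides rose at 8 of 34 with 0 falls (5 and 0 adjusted over the list alone; median 0.24, adjusted p = 0.0185, and 0.13 with a correlation of 0.05). Def was at log2 0.63 and CecC at 0.56 in the authors' deposited table. Cuticle genes gave 13 rises and 3 falls among 58, the same adjusted over the list alone (median 0.095, adjusted p = 0.00407, 0.0921 with a correlation of 0.05 and 0.0817 with ranks). The cuticle median ranked only at percentile 83.0 among random lists matched on mean normalized count. Cpr66D was at log2 2.22 ± 0.19 in the authors' deposited table. Cell cycle genes rose at 9 and fell at 2 of 28, the same adjusted over the list alone (median 0.24, adjusted p = 1.89e-05). Fzy was at log2 1.80, and the mitotic kinase genes aurB at 1.72 and Cdk1 at 1.69, in the authors' deposited table. In the piRNA and heterochromatin list 6 of 14 rose and 1 fell, the same adjusted over the list alone (median 0.21, adjusted p = 0.0058): aub (log2 1.40 ± 0.22) and piwi (1.34 ± 0.21), both piRNA Argonautes, rose in the authors' deposited table. The RNA interference gene AGO2 (log2 0.45) was among the called rises too. The reproductive list gave 10 rises and 2 falls among 32, the same adjusted over the list alone (median 0.15, adjusted p = 0.00745, and 0.0804 with a correlation of 0.05), and did not pass without the 5 genes named above (adjusted p = 0.0691).

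The sex-biased head list again passed through roX1 (2 rises and 2 falls among 14, the same adjusted over the list alone; median -0.065, adjusted p = 0.00625), and its ranks gave the opposite direction (adjusted p = 0.726). RoX2 stood at log2 0.26 ± 0.19, and Yp1, Yp2 and Yp3 at -0.38, -0.24 and -0.42, in the authors' deposited table, none past the threshold. Among KDM5 partners 3 of 16 rose and 1 fell, the same adjusted over the list alone (median 0.0080, adjusted p = 0.723): ash2, of histone methyltransferase complexes (log2 0.30), Sin3A (0.28) and MRG15 (0.31) rose and foxo fell (-0.25) in the authors' deposited table. Other demethylases gave 4 rises and 1 fall among 13, the same adjusted over the list alone (median -0.026, adjusted p = 0.295), with PSR at log2 0.81 in the authors' deposited table. In both mutants the demethylase and sex-biased lists had a median below 0 while their mean and test pointed up, and in JmjC* the fat body test pointed up against a median and mean below 0.

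**Figure D1:**
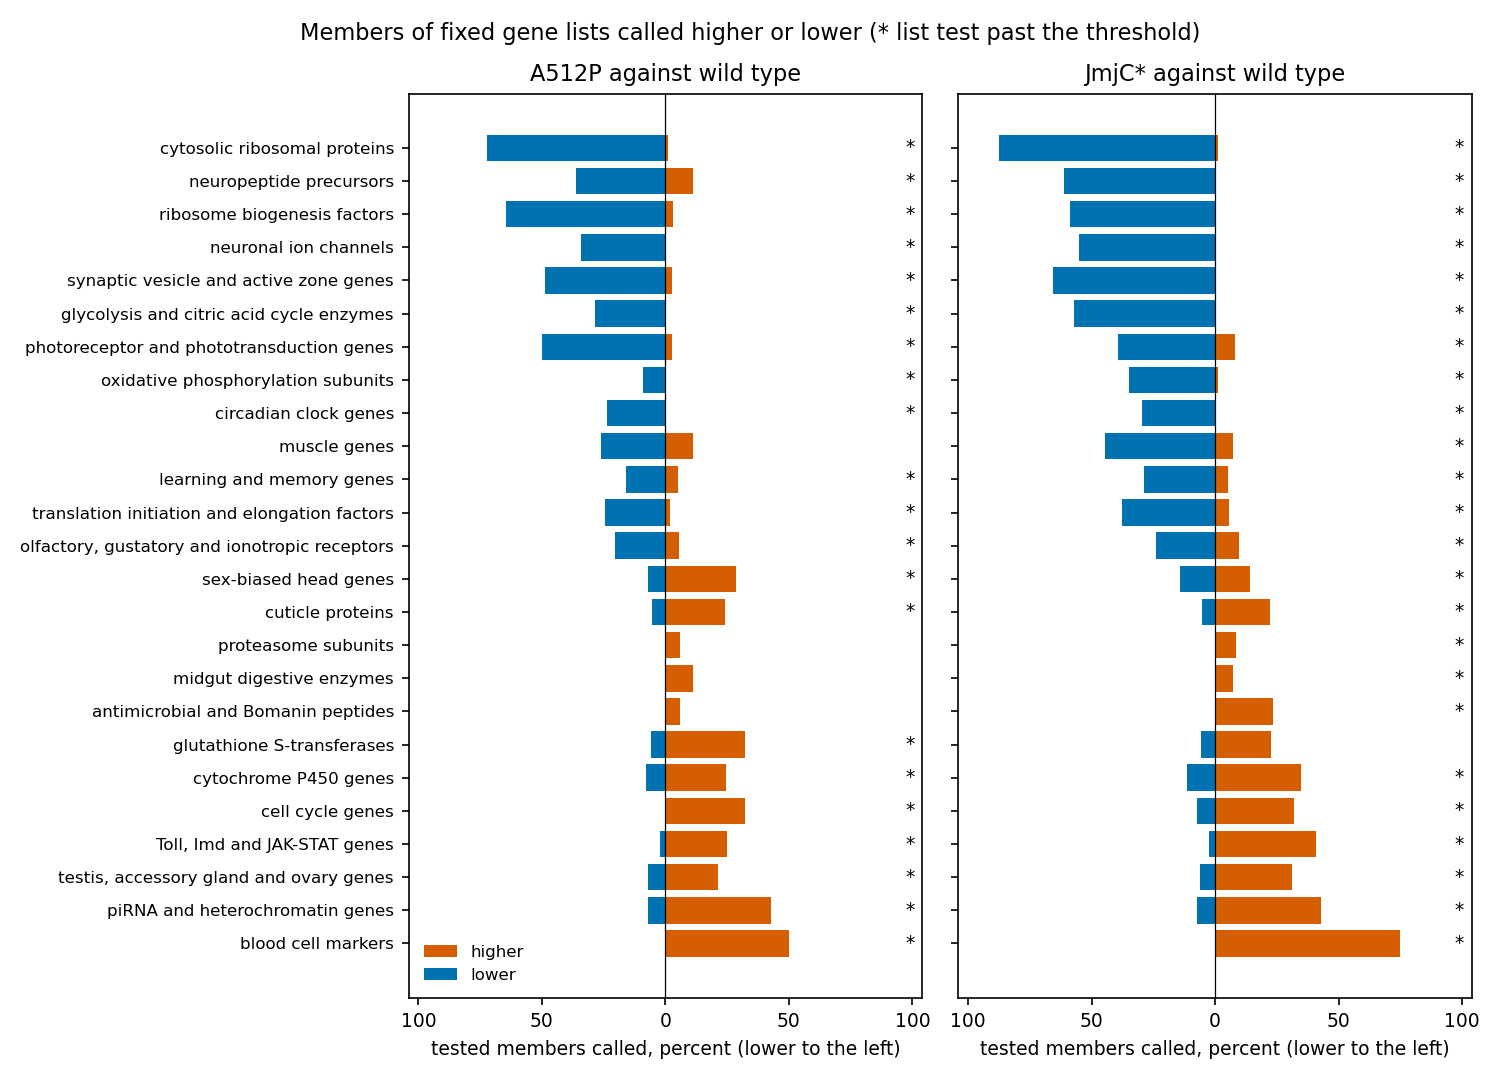
Percent of tested members of each gene list called higher (orange, right) or lower (blue, left) than wild type in A512P (left panel) and JmjC* (right panel), for the lists that passed the cameraPR test in at least 1 mutant (asterisk: passed in that panel). Cytosolic ribosomal proteins reach the largest lower share (62 of 86 and 76 of 87) and blood cell markers the largest higher share (8 and 12 of 16).

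Whether both alleles alter the same genes was asked over the 11608 genes tested in both tables. In both mutants 889 genes were higher by the authors' deposited tables, where independent lists would share 172 (odds ratio 36.5). Another 1029 were lower in both, where independent lists would share 187 (odds ratio 62.9). Both Fisher exact p-values were below the smallest number the software can hold. Of the 1929 genes called in both mutants, 1918 had the same direction and 11 the opposite one. The largest shared rises were roX1, CG13646, CycB, Klp61F, CG13720 and Cht3, a chitinase gene at log2 2.35 in A512P and 2.31 in JmjC*, and the largest shared falls Cyp4s3 and CG11349, at -2.52 and -2.54, all in the authors' deposited tables. CG11349 had a mean normalized count of 28.3.

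Both comparisons use the same wild-type libraries, which alone makes them alike. Across genes, which are not independent replicates, the scores of the mutants correlated at r = 0.834, against 0.50 in simulated unchanged groups with shared controls, and 82.4% of genes had the same sign, against 66.7% simulated. The covariance of the log2 fold changes was 0.113, against 0.0108 simulated, a difference of 0.103. The controls could not be split between the comparisons, so part of the excess over independent lists may come from the shared controls. The simulation covers only the random spread of those controls. A difference in strain background between the wild-type line and both mutant lines would enter both comparisons alike. For the shared changes it was not tested apart from the alleles.

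**Figure D2:**
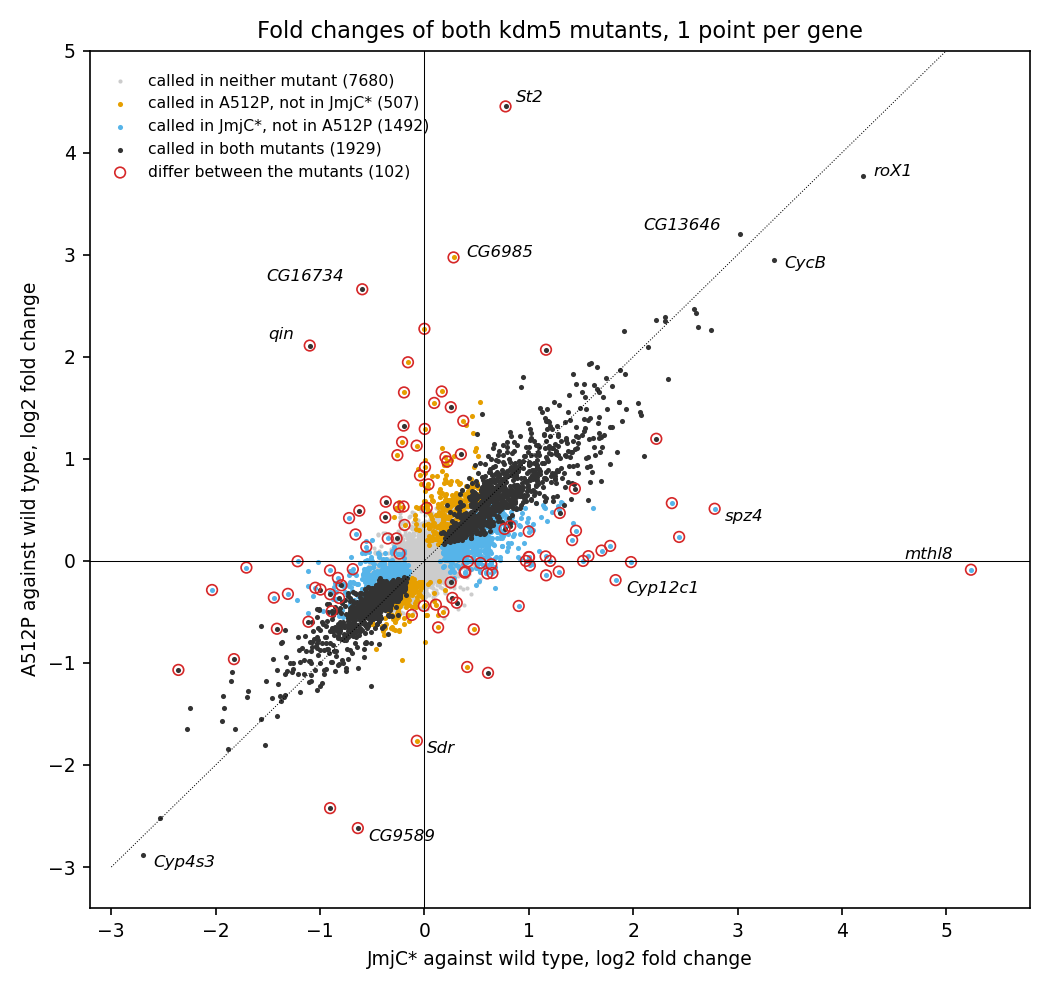
Log2 fold change against wild type in A512P (vertical axis) and JmjC* (horizontal axis) for the 11608 genes tested in both, 1 point per gene, coloured by the mutants in which the authors' deposited tables call it; the dotted line marks equal change. Red rings mark the 102 genes that differ between the mutants, such as St2 and qin (higher in A512P) and mthl8 (higher in JmjC*), while roX1, CycB and Cyp4s3 lie near the line.

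Tested against each other, the mutants differed at 102 of 11608 genes (0.879%), 54 higher and 48 lower in A512P than in JmjC*. St2 was higher in A512P by 3.68 ± 0.30 on the log2 scale (upper bound of the SE, adjusted p = 2.52e-31), CG16734 by 3.26 ± 0.25, qin, a piRNA pathway gene, by 3.21 ± 0.22 (adjusted p = 1.52e-43), CG6985 by 2.70 ± 0.25 and CR16735 by 2.27 ± 0.31. The genes qin and CG16734 went opposite ways: qin rose by 2.11 in A512P and fell by 1.10 in JmjC* in the authors' deposited tables, and CG16734 rose by 2.66 and fell by 0.60. CG6985 (3R, 22741150 to 22743081) overlaps the germline gene vret on the other strand, named outside the rule, which stood at log2 0.39 in A512P and 1.18 in JmjC* in the authors' deposited tables. Lower in A512P were mthl8 (-5.32 ± 0.31, adjusted p = 3.79e-61), spz4 (-2.27 ± 0.31), the P450 gene Cyp12c1 (-2.02 ± 0.23), CG9589 (-1.98 ± 0.31) and CG30440 (-1.71 ± 0.20). Opposite calls were also made for CG15353 (log2 0.49 in A512P, -0.62 in JmjC*), CG7203 (0.43, -0.37) and CG30033 (0.58, -0.37) in the authors' deposited tables.

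Of the 102 genes, 28 were called against wild type in A512P and not in JmjC*, 43 in JmjC* and not in A512P, and 31 in both. Conversely, of 507 genes called against wild type in A512P but not in JmjC*, the direct test called 28, and of 1492 called in JmjC* but not in A512P it called 43; for the rest a difference between the mutants was not shown. Among lists, neuropeptides differed most: the median of A512P minus JmjC* was 0.37 (35 of 36 genes higher in A512P, adjusted p = 6.41e-25), and 8 members were called directly, AstC by 0.75 ± 0.10 and Ms by 0.72 ± 0.13 among them. With the covariance of the shared wild type subtracted from the SE, 422 genes differed, 224 higher and 198 lower in A512P.

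Genes that differed between the mutants were not spread evenly over the genome. Chromosome arm 3R held 45 of the 102, at 1.58% of its tested genes against 0.651% elsewhere (Fisher exact test, odds ratio 2.44, adjusted p = 2.62e-04), and 2R held 9 (0.376% against 1.01%, adjusted p = 0.00872). Against wild type, A512P calls were more frequent on 3R (23.3% against 20.2% elsewhere, adjusted p = 0.00285) and less frequent on X (340 of 1891 genes, against 21.6% elsewhere, adjusted p = 0.00285). JmjC* calls were more frequent on chromosome 4 (43 of 101 genes, 42.6% against 28.7%, adjusted p = 0.0138). The other 13 of 18 arm tests did not pass. Within 1 Mb of kdm5 on 2L, 40 of 228 tested genes were called in A512P (17.5%, Fisher exact p = 0.218), 64 of 240 in JmjC* (26.7%, p = 0.517), and 2 of 228 differed between the mutants (p = 1.0).

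**Figure D3:**
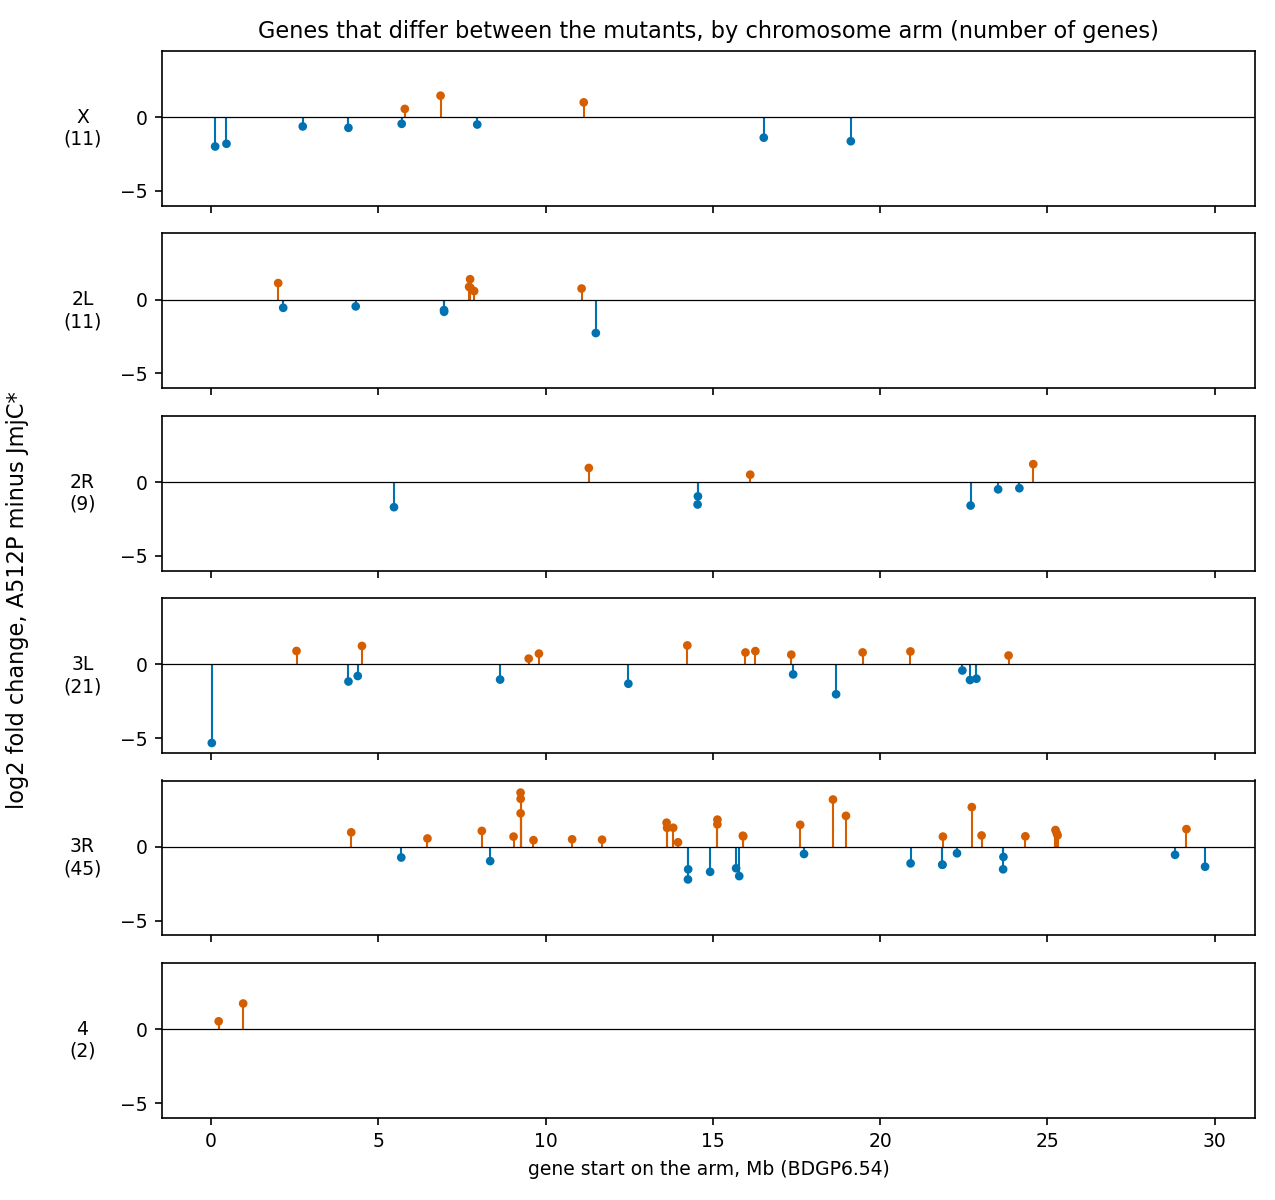
Position in Mb (BDGP6.54) and log2 difference, A512P minus JmjC*, of 99 of the 102 genes that differ between the mutants, by chromosome arm with the number of genes drawn; orange is higher and blue lower in A512P. Arm 3R carries 45 of them, with St2, CR16735 and CG16734 side by side.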

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

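In the weighings below, the tests of tissue share, ovary transcripts and replication against mitotic genes were chosen after the results they explain had been seen; the list tests of the difference and the tests of exon length, linkage and neighbouring genes were chosen before.

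Of the genes called against wild type in both mutants, 11, with 5 outside the rule for named genes (CG6912, CG6908, plx, kirre and bdl), had opposite directions. All 11 passed the direct test of the difference as well. Calls of opposite sign made that nearly certain in advance, since the direct test reuses the same fold changes and SEs. With the difference A512P minus JmjC* on the log2 scale, the genes higher in A512P were CG16734 (3.258), qin (3.2094), CG6912 (1.5263), CG15353 (1.1165), CG30033 (0.9505), CG7203 (0.8001) and CG6908 (0.4869). Lower in A512P were CG30440 (-1.7063), plx (-0.7194), the cell adhesion genes kirre (-0.6306) and bdl (-0.4625).

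Of the 37 lists, 7 differed between the mutants by the test of the difference (cameraPR, preset correlation of 0.01, adjusted over 37 tests). Whether these 7 calls hold with a preset correlation of 0.05 was not tested. Against wild type, that setting ended 20 list calls. The median of A512P minus JmjC* was 0.3684 for neuropeptides (35 of 36 genes higher in A512P, adjusted p = 6.41e-25), 0.1222 for oxidative phosphorylation (91 of 100, adjusted p = 8.43e-05) and 0.1071 for glycolysis and citric acid cycle (25 of 28, adjusted p = 0.0133). It was 0.0788 for muscle (23 of 27, adjusted p = 0.00893), 0.0748 for translation factors (41 of 53, adjusted p = 0.0261) and 0.0693 for synaptic genes (27 of 35, adjusted p = 0.0144). These 6 lists were less reduced in A512P than in JmjC*. Midgut digestive enzymes were lower in A512P (median -0.2388, 22 of 27 genes, adjusted p = 0.00308).

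Genes that differ between the mutants were concentrated on 3R, although kdm5 lies on 2L. The tables argue against neighbouring or overlapping genes being counted more than once: with differing genes within 20 kb counted once, 36 of 88 loci lay on 3R (40.9%, where 24.7% of tested genes lie; Fisher exact p = 7.35e-04). A linked stretch of different strain background on 3R stays open, since the median distance of a differing 3R gene to its nearest differing neighbour was 118 kb, against 203 kb in random draws of as many 3R genes (95% of 10000 draws 105 to 326 kb, one-sided permutation p = 0.0508). A candidate explanation is therefore background variation carried with the alleles; the labels do not give the strain crosses, and sequence variants were not analysed here. The alleles themselves, as the biological explanation the design names, were not separated from it.

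Synaptic, ion channel, cytosolic ribosome and ribosome biogenesis lists fell in both mutants. A trend with exon length or abundance, as the whole cause, is argued against: over these 4 lists in both comparisons, the highest percentile of a list median among random lists matched on both was 0.0. Matched lists had medians of -0.097 in A512P and -0.11 in JmjC* for synaptic genes, and -0.086 and -0.087 for ion channels. The values were -0.038 and -0.13 for cytosolic ribosomal proteins, and 0.019 and 0.028 for ribosome biogenesis. For the lists other than ribosome biogenesis, a part from such a trend stays open. A lower share of nervous tissue, with the other tissues kept in proportion, would raise markers of those tissues alike. These moved apart by more than their spread over genes: the muscle median was -0.098 (95% bootstrap interval -0.18 to 0.0046) in A512P and -0.23 (-0.32 to -0.10) in JmjC*, the blood cell median 0.26 (0.075 to 0.55) and 0.34 (0.18 to 0.71). A lower nervous share joined by changes in other tissues would also give such a split, so this comparison cannot decide on it. The fat body median was 0.19 (-0.051 to 0.24) in A512P and -0.025 (-0.15 to 0.0998) in JmjC*, and a change in the share of blood cells stays open. An effect of each allele on expression, the explanation the design names, was not tested apart from such changes in tissue share.

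The cell cycle list rose in both mutants, with 9 of 28 members called higher in each. In the piRNA and heterochromatin list 6 of 14 genes rose in each and del fell. Those rises include RNA interference genes, Dcr-2 in A512P and AGO2 in JmjC*. More cells passing through the cell cycle, as the whole cause, would raise DNA replication genes as much as the mitotic ones, but the median of 12 replication genes was -0.0076 (95% bootstrap interval -0.21 to 0.15) in A512P against 0.68 for 11 mitotic genes (permutation p = 0.00992), and 0.11 (-0.059 to 0.35) against 0.98 (p = 0.0133) in JmjC*. The JmjC* median lay above 0, as that cause predicts, and RnrS rose in both mutants (log2 1.02 and 1.16 in the authors' deposited tables), while PCNA, Mcm3, Mcm5 and Mcm7, expressed at about the level of fzy, were not called higher in either; a smaller part from cycling cells stays open. Ovary carried over with the heads stays open too: the ovary transcripts exu and Cp7Fc were called higher in both mutants at mean normalized counts of 133 and 91.7, while the highest of 11 others, osk and chorion genes among them, was 21.2, below the 268 of CycB, and 0 of the 7 tested passed. The effect of each allele, which the design names, was not tested apart from these.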

How the results depend on the processing

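No paired analysis was possible because the labels give no pairing and the tables used hold no values per library; for the same reason leaving out libraries, permuted splits of libraries, refits with other count models or filters, camera with an estimated correlation and fry were not run. The direction of each fold change rests on the name of its comparison, and the fold changes are shrunken. At an adjusted p under 0.01 the A512P calls fell to 1609 from 2436, and with a fold change of at least 1.5 they numbered 846 in A512P and 1138 in JmjC*; stricter thresholds can only remove calls. With the covariance of the shared wild type subtracted from the SE, the direct calls rose from 102 to 422, including all 102, since a smaller SE can only add calls. With a preset correlation of 0.05, 25 of 74 list tests passed in place of 45, since a larger correlation only widens each test. Ranks made 5 more list tests pass (in A512P the antimicrobial, mitochondrial ribosome, muscle and proteasome lists, in JmjC* the mitochondrial ribosome list) and ended 4 (chemoreceptors in A512P, cuticle in JmjC*, sex-biased head in both). A mean normalized count of at least 50 ended 4 list calls (chemoreceptors in both mutants, circadian and piRNA in A512P) and made the midgut list of A512P pass. Ranks turned the sex-biased head list in JmjC* downward (adjusted p = 0.726), as roX1 then counts as 1 rank. Under the other settings run, the calls ranged from 2228 to 3162 in A512P and from 2436 to 4181 in JmjC*. The direct calls ranged from 69, at an adjusted p under 0.01, to 128. Genes called in the same direction in both mutants numbered 1288 to 2482, and 42 to 46 list tests passed. Median-centred fold changes moved the share of calls that were higher from 48.6% to 52.7% in A512P and from 49.4% to 51.6% in JmjC*. Of 1745 alternatives for the named gene effects, 1710 left the call as it was, 35 ended it and 0 reversed it. Most of this was fixed in advance: the genes were mainly picked for a large change or a small adjusted p. Only median centring could change a sign, and an adjusted p under 0.1 cannot end a call.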

Other observations

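Chemoreceptor, glutathione S-transferase and cytochrome P450 lists gave calls that depended on the setting. Chemoreceptors fell at 18 and rose at 5 of 88 tested in A512P (21 and 6 adjusted over the list alone; median log2 -0.082, adjusted p = 0.0259). They fell at 24 and rose at 10 of 101 in JmjC* (26 and 10 adjusted over the list alone; median -0.16, adjusted p = 0.00667). With a preset correlation of 0.05 neither passed (adjusted p = 0.234 and 0.157), nor among genes with a mean normalized count of at least 50 (adjusted p = 0.986 and 0.832). The odorant receptor genes Or65b (log2 -1.84 in A512P, -1.88 in JmjC*) and Or67c (-1.44, -1.92) fell in the authors' deposited tables, at mean normalized counts of 18.9 and 48.9. Odorant-binding proteins did not pass, with 5 rises and 4 falls of 37 in A512P, the same adjusted over the list alone (median -0.030, adjusted p = 0.856), and 7 rises and 11 falls of 38 in JmjC* (8 and 12 adjusted over the list alone; median -0.036, adjusted p = 0.605). Obp56e fell in both (log2 -1.0, -1.09) and Obp83g rose in both (1.12, 1.20), in the authors' deposited tables. Glutathione S-transferases rose at 11 and fell at 2 of 34 in A512P (12 and 2 adjusted over the list alone; median 0.19, adjusted p = 0.00685, and 0.0804 with a correlation of 0.05). They gave 8 rises and 2 falls of 35 in JmjC* (8 and 3 adjusted over the list alone; median 0.16, adjusted p = 0.203). GstD2 was at log2 0.93 and 1.08, and GstE4 at -0.47 and -0.71, in the authors' deposited tables. Cytochrome P450 genes rose at 19 and fell at 6 of 77 in A512P (24 and 6 adjusted over the list alone). In JmjC*, 27 rose and 9 fell of 78 (28 and 10 adjusted over the list alone). Both P450 tests had a median of 0.18 and an adjusted p of 0.0126, and 0.168 with a correlation of 0.05. Cyp309a2 was at log2 1.12 and 1.62 in the authors' deposited tables. UDP-glycosyltransferases did not pass (4 rises and 1 fall of 26 in A512P, 4 and 0 adjusted over the list alone, median 0.0073, adjusted p = 0.618; 3 rises and 4 falls of 27 in JmjC*, the same adjusted over the list alone, median 0.039, adjusted p = 0.961).

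Midgut digestive enzymes rose as a list in JmjC*, with 2 rises and 0 falls of 27, the same adjusted over the list alone (median 0.27, adjusted p = 0.00492, and 0.0598 with a correlation of 0.05). In A512P the list gave 3 rises and 0 falls of 27, the same adjusted over the list alone (median -0.0060, adjusted p = 0.306), and it passed upward among genes with a mean normalized count of at least 50 (adjusted p = 0.0247). The amylase genes Amy-d (log2 1.55 in A512P, 1.87 in JmjC*) and Amy-p (1.49, 1.75) rose in both mutants in the authors' deposited tables. Heat shock proteins gave 2 rises and 2 falls of 22 in each mutant, the same adjusted over the list alone (median -0.042, adjusted p = 0.791 in A512P; 0.048, adjusted p = 0.907 in JmjC*): Hsp83, a chaperone, was at log2 0.91 in both and Hsc70-1 at -1.0 in both, in the authors' deposited tables. Antioxidant enzymes gave 3 rises and 1 fall of 23 in A512P (median -0.040, adjusted p = 0.899) and 3 rises and 3 falls in JmjC* (median -0.075, adjusted p = 0.791), the same adjusted over the list alone. Hormone genes gave 4 rises and 3 falls of 29 in A512P (median -0.044, adjusted p = 0.791) and 3 rises and 8 falls in JmjC* (median -0.12, adjusted p = 0.247), the same adjusted over the list alone. Eip71CD, an ecdysone-induced gene, was at log2 -0.71 and -0.82 in the authors' deposited tables. Storage and lipid genes gave 3 rises and 4 falls of 24 in A512P, the same adjusted over the list alone (median -0.015, adjusted p = 0.619), and 3 rises and 6 falls in JmjC* (5 and 6 adjusted over the list alone; median -0.053, adjusted p = 0.584). The lipase gene bmm was at log2 0.42 in A512P in the authors' deposited table. Histone genes gave 1 fall and 0 rises of 7 in A512P (median 0.032, adjusted p = 0.723) and 2 falls and 1 rise in JmjC* (median -0.041, adjusted p = 0.743), the same adjusted over the list alone; 1 member, CG1358 (log2 -0.40 and -0.26 in the authors' deposited tables), encodes a transporter and was taken by its name. In A512P the median and the mean had opposite signs for the heat shock, antioxidant, hormone, odorant-binding, histone and digestive lists, and in JmjC* for the odorant-binding list.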
